A study of Bos taurus with 15 samples.

How the data were processed

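Gene expression was measured with Affymetrix bovine gene arrays on total RNA from BFH12 cells, a line made from fetal bovine hepatocytes by transduction with the SV40 large T antigen. The 15 arrays fell into 3 groups of 5: medium with vehicle (0.1% DMSO), tunicamycin at 100 ng/mL (TM) and thapsigargin at 100 nM (TG), each for 24 h per the labels' protocols. Tunicamycin blocks the first step of N-glycan assembly, and thapsigargin blocks the calcium pump of the endoplasmic reticulum (ER). Whether the TM and TG media also held DMSO, and whether arrays of a group came from separate cultures, is not given in the sources used here.

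The authors' deposited table gives log2 values per probe set and array, made with RMA in Affymetrix Expression Console 1.4 per the submitters' processing notes. Background, summarization and annotation settings are not given. The table held 24333 probe sets and none of a control category. A second deposited table held the same log2 values rounded, and every value lay within 0.005 of the first. The deposited p-value and mean log2 difference of each probe set, computed by the authors, were read only for a comparison of counts and a check against the log2 values. The authors' test is not named in the sources used here. Their p-values matched an equal-variance t-test on the log2 values, with the largest difference in log10 p at 1.7e-12 for TM against vehicle.

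Gene symbols were set through the RefSeq accession in the deposited table (14673 probe sets), through the symbol (3790) or through a synonym (79), with a bovine RefSeq gene table used for names alone. The symbol of the deposited table stood for 1879 probe sets, and 3912 had no gene symbol. Of 20062 distinct symbols, 341 had several probe sets, and 1136 probe sets were marked as open to cross-hybridization. Coordinates are those of the deposited table, which names no genome build.

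Each probe set was fitted with limma 3.58.1 in R 4.3.3, with 1 coefficient per group over all 15 arrays and moderated variances. The comparisons were TM against vehicle, TG against vehicle and TM against TG. The p-values were two-sided and adjusted by Benjamini-Hochberg over the 24333 probe sets, with a threshold of 0.05. Probe sets of low signal were kept. A probe set counted as having its groups apart when all 5 arrays of one group lay above all 5 of the other. The p-values measure only the spread between these arrays, and the number of arrays limits their precision.

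The tests, their alternatives, the naming rule and 25 gene lists were fixed before the data were examined. The lists covered ER chaperones and folding enzymes, ER-associated degradation, sensors of the unfolded protein response, PERK-ATF4-CHOP targets, amino acid synthesis and transport, cytosolic aminoacyl-tRNA synthetases, ER translocation, N-glycan precursor synthesis, ER-Golgi transport and ER calcium handling. They further covered cholesterol synthesis, fatty acid synthesis, fatty acid oxidation, gluconeogenesis, hepatocyte markers, acute phase genes, NRF2 targets, apoptosis regulators, the cell cycle, p53 targets, heat shock genes and autophagy. Markers of fibroblasts, of cholangiocytes, and of endothelium and macrophages stood for other liver cell types. Each list was tested with limma camera at a preset correlation between genes of 0.01, with 1 probe set per gene (the one with the highest mean) and adjustment over the 25 lists. The same test with a correlation estimated for each list, camera on ranks, and fry, which asks whether a list moves on balance in one direction, were run beside it. Camera compares a list with the other genes. Fry sets a list against no change at all, so a few strongly changed members can be enough for a call. Members past the threshold were counted over all probe sets and adjusted over the list alone.

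Genes were named by a rule with 3 parts. The first took the 8 largest rises and the 8 largest falls per comparison among called probe sets with groups apart, passing over provisional names. The next part took 14 fixed genes in each comparison, changed or not (HSPA5, HSP90B1, HERPUD1, XBP1, ATF4, DDIT3, ATF3, TRIB3, ASNS, FGF21, DPAGT1, ATP2A2, HMGCS1 and ALB). The last took the 2 members with the largest change in each list with 3 or more called members. The rule gave 68, 73 and 59 genes for the 3 comparisons. List members named as exceptions to the direction of their list stand outside this rule and were chosen after their values were seen.

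Overlap between TM and TG was set beside 50 simulations of unchanged groups with shared vehicle arrays, beside the number that independent lists would give, and beside 20 divisions of the vehicle arrays between both comparisons. Other splits of the arrays were drawn 100 times. The code was tested on simulated data: for TM against vehicle over 24333 probe sets, it recovered a share of 0.57 of probe sets changed by 0.5 log2 and 0.99 of those changed by 1, and a share of 0.037 of its calls was false. In the same simulated comparison over 20062 genes, the camera tests and fry each called the 1 list of 27 genes shifted by 0.25 log2 and no other. The simulated noise was independent between genes, so this does not test lists whose members vary together. On the real arrays the estimated correlation was 0.302 for the cholesterol list.

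Alternatives covered the replicate number as a block, a filter on the dimmest probe sets (a share of 0.333), cyclic loess, median centring, the rounded table, other variance models, array weights, the 10 arrays of each pair of groups, 1 probe set per gene, a 2-fold minimum and leaving out each array. A covariate for the width of each array's values and a fit without TM array 4 and TG array 1 were added after seeing the data. Random blocks used statmod 1.5.0. Permutation tests were run in R. Tables were made in R and in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots with matplotlib 3.10.9. No array was left out of the reported values, and the scans behind the values were not used.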

Results

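The study asked what ER stress, induced with TM or TG, does to gene expression in a bovine liver cell model (the series title spells the line BHF12). Expression was measured on 15 arrays, 5 each for vehicle, TM and TG, at 24 h. The deposited RMA values ranged from 1.27 to 14.98 on the log2 scale, with array medians of 7.44 to 7.6. The number of arrays limits the precision of every value. All values below are log2 signals, given as the mean with its SD, and changes are differences of log2 means with their standard error (SE).

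TM was set against vehicle to ask which genes respond when N-glycan assembly is blocked. Genes of protein folding in the ER (26 of 27), of ER-associated degradation (16 of 22), of the PERK-ATF4-CHOP branch (17 of 18) and of amino acid supply (17 of 20) rose. Of the cholesterol genes, 20 of 24 fell, led by HMGCS1, the enzyme that makes HMG-CoA for the mevalonate pathway, from 12.09 ± 0.07 (SD, n = 5) to 9.30 ± 0.12 (SD, n = 5), a 6.90-fold fall. DDIT3, which encodes the stress transcription factor CHOP, rose 5.04-fold, from 9.01 ± 0.14 (SD, n = 5) to 11.35 ± 0.13 (SD, n = 5). The chaperone gene HSPA5 (BiP) rose 1.87-fold from a level already near the top of the scale, from 13.50 ± 0.06 (SD, n = 5) to 14.41 ± 0.05 (SD, n = 5). Of 24333 probe sets, 4979 passed the threshold in limma, 2476 higher and 2503 lower with TM.

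The groups were apart for 4296 probe sets, or 17.7% where chance gives 0.794%. A change of at least 2-fold was seen for 148 higher and 86 lower probe sets. In the authors' deposited table, 6966 probe sets had an unadjusted p under 0.05 for the same comparison, and 4618 after Benjamini-Hochberg adjustment.

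The largest rise was that of CYP3A74, a drug-metabolizing cytochrome P450 that the deposited table names CYP3A4. Its probe set 12816039 (chromosome 25, 37125929 to 37175162, minus strand) went from 7.25 ± 0.14 (SD, n = 5) to 10.65 ± 0.05 (SD, n = 5), a change of 3.40 (SE 0.098, adjusted p = 3.6e-12). Other members of the CYP3A family are close in sequence, so which member the signal came from is uncertain. RCAN1, a regulator of calcineurin (chromosome 1, 351708 to 362908, plus strand), rose by 3.33 (SE 0.062, adjusted p = 4.21e-14). Of the others, the cilia assembly gene CCDC39 rose 9.85-fold, TNFSF18, a ligand of the TNF family, 8.74-fold, and SYT4, a calcium sensor of vesicles, 7.83-fold. The interferon-induced gene IFIT1 rose 7.25-fold, though which IFIT gene gave the signal is uncertain, DNAJB9, a co-chaperone of BiP, 5.18-fold, and the prostaglandin synthase gene PTGS2 5.12-fold. All 5 TM arrays lay above all 5 vehicle arrays for each of these genes.

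The deepest fall was that of PLET1, a surface glycoprotein gene (chromosome 15, 22978370 to 22990478, minus strand), with a change of -3.39 (SE 0.238, adjusted p = 5.61e-08), from 11.67 ± 0.56 (SD, n = 5) to 8.29 ± 0.26 (SD, n = 5). It was followed by HMGCS1 (chromosome 20, 31451299 to 31477033, plus strand; SE 0.086, adjusted p = 6.16e-12) and by LRRN4, a leucine-rich repeat gene, which was 6.20-fold lower. The chemokine genes CXCL9 and CXCL11 were 5.82-fold and 4.30-fold lower, the fatty acid-binding protein gene FABP3 4.79-fold, the carbonic anhydrase gene CA3 4.73-fold. The keratin gene KRT6A, one of a family of similar keratins, went from 7.03 ± 0.36 (SD, n = 5) to 5.01 ± 0.32 (SD, n = 5), below the lower quartile of the arrays, so the size of its fall is uncertain. All 5 TM arrays lay below all 5 vehicle arrays for each of these genes.

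ER chaperones and folding enzymes rose almost without exception with TM. Of 27 measured members, 26 rose and only FKBP14, a prolyl isomerase gene, fell, with the same counts adjusted over the list alone (median change 0.82; camera adjusted p = 3.43e-33). SDF2L1, a partner of BiP, rose by 2.22 and HSP90B1 (GRP94) by 0.80. In ER-associated degradation, which removes misfolded proteins, 16 of 22 rose and NPLOC4 fell (17 and 2 adjusted over the list alone; adjusted p = 5.03e-14), led by DERL3 at 2.32 and HERPUD1 at 2.11. The PERK-ATF4-CHOP list had 17 of 18 members up and none down, the same adjusted over the list alone (median 1.14; adjusted p = 1.78e-24). Beside DDIT3, the pseudokinase gene TRIB3 rose by 2.15, ATF4 by 0.61, ATF3 by 0.57 and the hormone gene FGF21 by 0.45 (adjusted p = 0.00369).

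Of 20 genes of amino acid synthesis and transport, 17 rose and ALDH18A1 and SLC7A5 fell, the same adjusted over the list alone (adjusted p = 3.02e-17). The mitochondrial folate enzyme gene ALDH1L2 rose by 2.13, the cystine transporter gene SLC7A11 by 2.09 and the asparagine synthetase gene ASNS by 0.84. N-glycan precursor synthesis, the pathway that TM blocks, had 25 of 32 members up and none down (27 and 1 adjusted over the list alone; adjusted p = 1.06e-15). Its first enzyme and the target of TM, DPAGT1, rose by 1.36, from 10.55 ± 0.12 (SD, n = 5) to 11.92 ± 0.08 (SD, n = 5), and SRD5A3, which makes dolichol, by 1.05. ER translocation genes rose in 13 of 22 cases (15 with 1 fall adjusted over the list alone; adjusted p = 1e-09), led by the signal peptidase gene SEC11C at 1.4 and the channel gene SEC61A1 at 0.91. Of 24 ER calcium genes, 13 rose and RCN3 fell (15 and 1 adjusted over the list alone; adjusted p = 7.13e-08). Beside RCAN1, the calcium-binding protein gene RCN2 went from 9.70 ± 0.09 (SD, n = 5) to 11.33 ± 0.09 (SD, n = 5), and the calcium pump gene ATP2A2 rose by 0.64.

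Of 24 genes of cholesterol synthesis and uptake, 20 fell with TM and only the sterol carrier gene STARD4 rose (21 and 1 adjusted over the list alone; median change -1.05, adjusted p = 3.02e-25). Beside HMGCS1, the squalene epoxidase gene SQLE fell by 1.99 on the log2 scale. Fatty acid and triacylglycerol synthesis had 9 of 23 members down and 3 up (10 and 5 adjusted over the list alone; adjusted p = 0.00259), and this call ended with camera on ranks (adjusted p = 0.0847). The desaturase gene SCD fell by 1.89 on the log2 scale, and FADS2 went from 9.83 ± 0.09 (SD, n = 5) to 8.13 ± 0.27 (SD, n = 5). The members that rose were the elongase gene ELOVL5, the triacylglycerol synthesis gene DGAT1 and the lipid droplet gene PLIN2. The 9 lists of these paragraphs, from ER chaperones to fatty acid synthesis, were those that passed with an estimated correlation, with adjusted p from 6.19e-05 to 0.0403.

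A further 9 lists passed camera with TM but not with an estimated correlation. Sensors of the unfolded protein response rose in 6 of 12 cases and 2 fell (7 and 2 adjusted over the list alone; camera adjusted p = 0.00606, adjusted p = 0.097 with an estimated correlation and 0.0506 on ranks), among them ATF6 at 0.92 and EIF2AK3, which encodes PERK, at 0.73. The transcription factor gene XBP1 rose by 0.32, and its probe set does not tell the spliced from the unspliced form. The tRNA synthetases rose in 10 of 18 cases and fell in 4, the same adjusted over the list alone (adjusted p = 0.0699 with an estimated correlation), with WARS1 up by 1.18 and GARS1 by 0.96. ER-Golgi transport had 16 of 29 up and 5 down, the same adjusted over the list alone (adjusted p = 0.0828 with an estimated correlation), with PREB up by 0.75 and ARFGAP3 by 0.68. Autophagy genes rose in 13 of 23 cases and ATG3 fell (15 and 1 adjusted over the list alone; adjusted p = 0.0587 with an estimated correlation), with ATG13 up by 1.10 and GABARAPL1 by 0.62. Acute phase genes rose in 10 of 28 cases and fell for C3, the complement component, and LIF (11 and 2 adjusted over the list alone; adjusted p = 0.0699 with an estimated correlation). The p53 targets rose in 7 of 16 cases and fell in 2 (8 and 3 adjusted over the list alone; adjusted p = 0.173 with an estimated correlation), with FAS up by 0.74 and the cell cycle inhibitor gene CDKN1A by 0.74.

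Lists that moved down in the same way were NRF2 targets, heat shock genes and the cell cycle. Of 22 NRF2 targets, 12 fell and SLC7A11 and UGDH rose (15 and 3 adjusted over the list alone; adjusted p = 0.0608 with an estimated correlation), with the transketolase gene TKT down to -0.78 relative to vehicle. Cytosolic and mitochondrial heat shock genes fell in 11 of 19 cases and HSPA9 rose (11 and 2 adjusted over the list alone; adjusted p = 0.151 with an estimated correlation), among them HSPH1 at -0.55 and HSPE1 at -0.54. Cell cycle genes fell in 10 of 35 cases, with CDC25A at -0.59, and rose for CDC6 at 0.52 and CDC25C (12 and 2 adjusted over the list alone; adjusted p = 0.293 with an estimated correlation), a call that also ended with cyclic loess (adjusted p = 0.118) and without TM array 4 and TG array 1 together (0.0537).

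Of the remaining 7 lists with TM, fry, which does not compare a list with the other genes, called 4. Gluconeogenesis (fry adjusted p = 0.000891) and apoptosis regulators (0.0107) moved up in it. Fibroblast genes (4.97e-05) and cholangiocyte genes (1.37e-06) moved down. None of the 7 passed camera, whose adjusted p follows. Fatty acid oxidation had 2 up and 5 down of 26 (the same adjusted over the list alone; adjusted p = 0.393), gluconeogenesis 3 up and 2 down of 16 (the same adjusted over the list alone; 0.369) and apoptosis regulators 6 up and 2 down of 23 (the same adjusted over the list alone; 0.117, but 0.0408 without TM array 4 and 0.0455 without TM array 4 and TG array 1). Single members still moved: CPT1A, which brings fatty acids into mitochondria, rose by 0.42, the lipase inhibitor gene ANGPTL4 by 0.36, PCK2, the mitochondrial PEP carboxykinase gene, 2.37-fold, the aminotransferase gene GOT1 by 0.59, the inhibitor of apoptosis gene BIRC3 by 1.34 and the BH3-only gene PMAIP1 by 1.03. Hepatocyte markers had 3 up and 5 down of 28 (3 and 6 adjusted over the list alone; 0.467), with the fibrinogen gene FGG up 2.65-fold and the apolipoprotein gene APOA1 down to -0.94 relative to vehicle. The albumin gene ALB lay below the lower quartile of the arrays, at 4.88 ± 0.11 (SD, n = 5) in vehicle and 4.89 ± 0.12 (SD, n = 5) with TM (adjusted p = 0.973). Of the markers of other cell types, fibroblast genes had 2 up and 5 down of 16 (2 and 6 adjusted over the list alone; adjusted p = 0.23), with TAGLN at -0.73 and ACTA2 at -0.60. The cells were of 1 line, and its vehicle arrays were bright for both genes. TAGLN lay between 13.098 and 13.255 there, and ACTA2 between 13.531 and 13.663. Cholangiocyte genes had 4 down of 10 (the same adjusted over the list alone; 0.0503), with the keratin gene KRT19 at -1.22 and the osteopontin gene SPP1 at -1.15. That list passed without vehicle array 1 (0.048), 2 (0.048), 3 (0.0438) or 5 (0.0466), or without TM array 4 (0.0291), and also without TM array 4 and TG array 1 together (0.0361) and without the dimmest probe sets (0.0192). Endothelial and macrophage genes had 2 down of 14, LYVE1 and CD68 (the same adjusted over the list alone; 0.301).

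**Figure D1:**
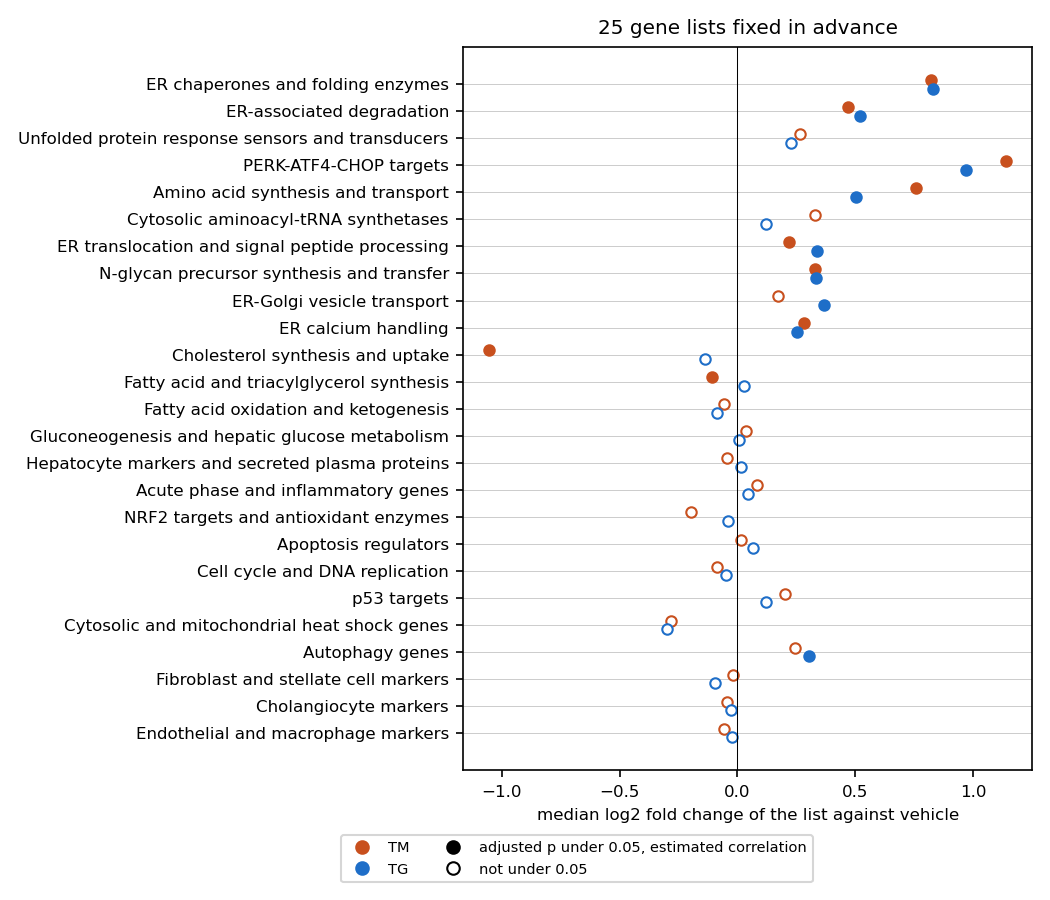
Median log2 fold change of each of the 25 gene lists against vehicle (horizontal axis, log2), with TM in orange and TG in blue, and filled points for lists that passed camera with an estimated correlation. ER stress lists lay to the right of 0 with both compounds, while cholesterol synthesis lay at -1.05 with TM and -0.14 with TG.

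TG was set against vehicle to ask which genes respond when the ER calcium pump is blocked. Genes of ER folding (25 of 27), degradation (18 of 22), N-glycan synthesis (25 of 32) and the PERK-ATF4-CHOP branch (17 of 18) rose with TG as well, with HSPA5 at 14.41 ± 0.04 (SD, n = 5) against 13.50 ± 0.06 (SD, n = 5), a 1.88-fold rise. The largest rise was that of MX1, an antiviral GTPase gene induced by interferon, from 6.17 ± 0.18 (SD, n = 5) to 10.21 ± 0.30 (SD, n = 5), or 16.5-fold, a size that is uncertain since its vehicle signal lay near the lower quartile of the arrays. The chemokine genes CXCL9, CXCL10 and CXCL11 fell, CXCL10 from 10.90 ± 0.12 (SD, n = 5) to 8.75 ± 0.27 (SD, n = 5). HMGCS1 fell 1.39-fold, to 11.61 ± 0.19 (SD, n = 5). In limma, 5063 probe sets passed, 2442 higher and 2621 lower with TG.

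The groups were apart for 4430 probe sets, or 18.2% where chance gives 0.794%. A change of at least 2-fold was seen for 146 higher and 81 lower probe sets. In the authors' deposited table, 6968 probe sets had an unadjusted p under 0.05, and 4760 after Benjamini-Hochberg adjustment.

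MX1 (probe set 12678517, chromosome 1, 143172672 to 143204866) rose by 4.05 (SE 0.134, adjusted p = 1.67e-11). RCAN1 rose 12.1-fold (SE 0.062, adjusted p = 1.34e-14) and IFIT1 11.9-fold (SE 0.111, adjusted p = 8.37e-12). The antiviral oligoadenylate synthetase gene OAS1Y went from 6.13 ± 0.15 (SD, n = 5) to 9.58 ± 0.44 (SD, n = 5), a gene with close relatives, so which of them gave the signal is uncertain. SYT4 rose 7.97-fold, CYP3A74 7.38-fold, CCDC39 5.75-fold and the transcription cofactor gene LBH 5.51-fold. Among the falls, CXCL9 was 9.35-fold lower (SE 0.131, adjusted p = 1.39e-10), PLET1 6.95-fold, CXCL11 5.12-fold, SCEL, a gene of the epidermal envelope, 4.67-fold, CXCL10 4.44-fold, CA3 4.39-fold and the serpin gene SERPINI1 4-fold. KRT6A fell to 4.80 ± 0.36 (SD, n = 5), also below the lower quartile of the arrays. For each of these genes, the 5 TG arrays and the 5 vehicle arrays did not overlap.

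With TG, 25 of 27 ER chaperones rose and none fell (26 and 0 adjusted over the list alone; median 0.83; camera adjusted p = 1.14e-33), with SDF2L1 up by 2.38, CRELD2, a folding factor, by 2.23 and HSP90B1 by 0.83. In ER-associated degradation, 18 of 22 rose and none fell, the same adjusted over the list alone (adjusted p = 5.4e-18), with DERL3 up by 2.25 and HERPUD1 by 2.12. PERK-ATF4-CHOP targets rose in 17 of 18 cases, the same adjusted over the list alone (median 0.97; adjusted p = 4.17e-21): DDIT3 by 2.14, the stress protein gene NUPR1 by 1.74, TRIB3 by 1.70, ATF3 by 0.53 and ATF4 by 0.52. FGF21 rose by 0.34 (adjusted p = 0.0241), and this call ended without vehicle array 3 (0.0618), vehicle array 5 (0.0685) or TG array 4 (0.0691). Amino acid genes rose in 15 of 20 cases and fell for ALDH18A1 and SLC7A5, the same adjusted over the list alone (adjusted p = 2.06e-12), with ALDH1L2 up by 2.21, SLC7A11 by 2.00 and ASNS by 0.67.

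N-glycan precursor genes rose in 25 of 32 cases with TG and none fell (27 and 0 adjusted over the list alone; adjusted p = 4.09e-16), with DPAGT1 up by 1.10 and the mannosyltransferase gene ALG12 by 0.80. ER translocation genes rose in 14 of 22 cases (15 adjusted over the list alone; adjusted p = 5.57e-11), with SEC11C at 1.47 and SEC61A1 at 0.96. ER-Golgi transport genes rose in 22 of 29 cases and none fell (23 and 1 adjusted over the list alone; adjusted p = 7.26e-14), with the coat protein gene COPE at 0.73 and ARFGAP3 at 0.72. Of 24 ER calcium genes, 13 rose and the calcium channel gene ITPR3 fell, the same adjusted over the list alone (adjusted p = 6.74e-09), with NUCB2 up by 1.70 and ATP2A2, which encodes the pump that TG blocks, by 0.60. Autophagy genes rose in 15 of 23 cases and ATG3 fell to -0.70 relative to vehicle (16 and 1 adjusted over the list alone; adjusted p = 3.25e-07), with ATG13 up by 1.18. These 9 lists, from ER chaperones to autophagy, also passed with an estimated correlation, with adjusted p from 0.00013 to 0.0435.

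A further 4 lists passed camera with TG but not with an estimated correlation. Cholesterol genes fell in 11 of 24 cases and rose for EBP and STARD4 (11 and 4 adjusted over the list alone; camera adjusted p = 0.000211, and adjusted p = 0.268 with an estimated correlation), with ACAT2 at -0.63, SQLE at -0.50 and HMGCS1 at -0.48 (adjusted p = 0.000667). Heat shock genes fell in 12 of 19 cases and HSPA9 rose (12 and 2 adjusted over the list alone; adjusted p = 0.11 with an estimated correlation), with HSPH1 at -0.75 and HSPE1 at -0.60. Sensors of the unfolded protein response rose in 6 of 12 cases and EIF2S1, a translation initiation factor gene, fell (6 and 2 adjusted over the list alone; adjusted p = 0.0949 with an estimated correlation and 0.0562 on ranks), with ATF6 up by 1.06, EIF2AK3 by 0.79 and XBP1 by 0.32. The tRNA synthetases rose in 9 of 18 cases and fell in 4, the same adjusted over the list alone (adjusted p = 0.199 with an estimated correlation and 0.109 on ranks), with WARS1 up by 1.25 and GARS1 by 0.81.

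Of the other 12 lists with TG, fry called 5. Acute phase genes (fry adjusted p = 0.0056) and p53 targets (0.0024) moved up in it. The cell cycle (0.0305), fibroblast genes (5.08e-07) and cholangiocyte genes (2.56e-05) moved down. None of the 12 passed camera, whose adjusted p follows. Fatty acid synthesis had 3 up and 5 down of 23, the same adjusted over the list alone (adjusted p = 0.679), with DGAT1 at 0.88 and the elongase gene ELOVL6 going from 11.10 ± 0.07 (SD, n = 5) to 10.51 ± 0.13 (SD, n = 5). Its median was 0.03 while its mean was -0.03 and its test pointed down. Fatty acid oxidation had 4 up and 5 down of 26, the same adjusted over the list alone (0.439), with CPT1A at 0.84 and EHHADH at -0.51. Gluconeogenesis had 3 up and 2 down of 16, the same adjusted over the list alone (0.802), with PCK2 at 1.00 and the glucose transporter gene SLC2A2 at -0.74. Hepatocyte markers had 4 up and 5 down of 28, the same adjusted over the list alone (0.679; a positive median beside a mean of -0.02 and a test that pointed down), with FGG at 1.39 and APOA1 at -1.14. ALB stood at 4.86 ± 0.30 (SD, n = 5) with TG (adjusted p = 0.951). Acute phase genes had 6 up and 4 down of 28, the same adjusted over the list alone (0.257), with PTGS2 at 1.55 and C3 at -1.34. NRF2 targets had 3 up and 6 down of 22 (3 and 9 adjusted over the list alone; 0.322), with SLC7A11 the largest rise and the thioredoxin reductase gene TXNRD1 at -0.71.

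Apoptosis regulators had 7 up and 5 down of 23 with TG (10 and 5 adjusted over the list alone; adjusted p = 0.201), with PMAIP1 at 0.90 and the BH3-only gene BMF at 0.61. The p53 targets had 6 up and 4 down of 16, the same adjusted over the list alone (0.132), with CDKN1A at 0.88 and the kinase gene PLK3 at 0.63. Cell cycle genes had 2 up and 9 down of 35 (3 and 12 adjusted over the list alone; 0.0834, and 0.0393 without TG array 5), the rises being CDC6 at 0.43 and the phosphatase gene CDC25C at 0.43. Fibroblast genes had 2 up and 5 down of 16 (2 and 7 adjusted over the list alone; 0.0638, and 0.0359 without vehicle array 2), with TAGLN at -1.06 and ACTA2 at -0.73. Cholangiocyte genes had 1 up, CFTR, and 2 down of 10, KRT19 at -1.22 and SPP1 at -1.06, the same adjusted over the list alone (0.238). Endothelial and macrophage genes had 1 down of 14, KDR, the same adjusted over the list alone (0.679).

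The overlap of both responses asks how far TM and TG act on the same genes. HERPUD1, DDIT3, RCAN1 and ALDH1L2 were among 1768 probe sets higher with both compounds, and CXCL9, PLET1, CA3 and KRT19 among 1865 lower with both. In all, 3633 probe sets changed in the same direction and 40 in opposite directions, 73.0% of the calls with TM and 71.8% of those with TG. At least 2-fold in both were 139.

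Independent lists of the same lengths would share 248 higher and 270 lower probe sets. Both comparisons share the 5 vehicle arrays, and in 50 simulations of unchanged groups with shared vehicle arrays no probe set was called in both. With no changed gene, hardly any probe set could be called there, so this count cannot show how far shared arrays raise the overlap. Across probe sets, which are not independent replicates, the log2 fold changes of TM and TG had a Pearson r of 0.791, against 0.5 in the simulations. Their covariance was 0.0633, against 0.00884 in the simulations, a difference of 0.0544 that estimates the shared effect. With the vehicle arrays divided between the comparisons, which leaves 2 or 3 vehicle arrays in each, the number shared had a median of 2333, from 2249 to 2483 over 20 divisions, and r a median of 0.616.

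**Figure D2:**
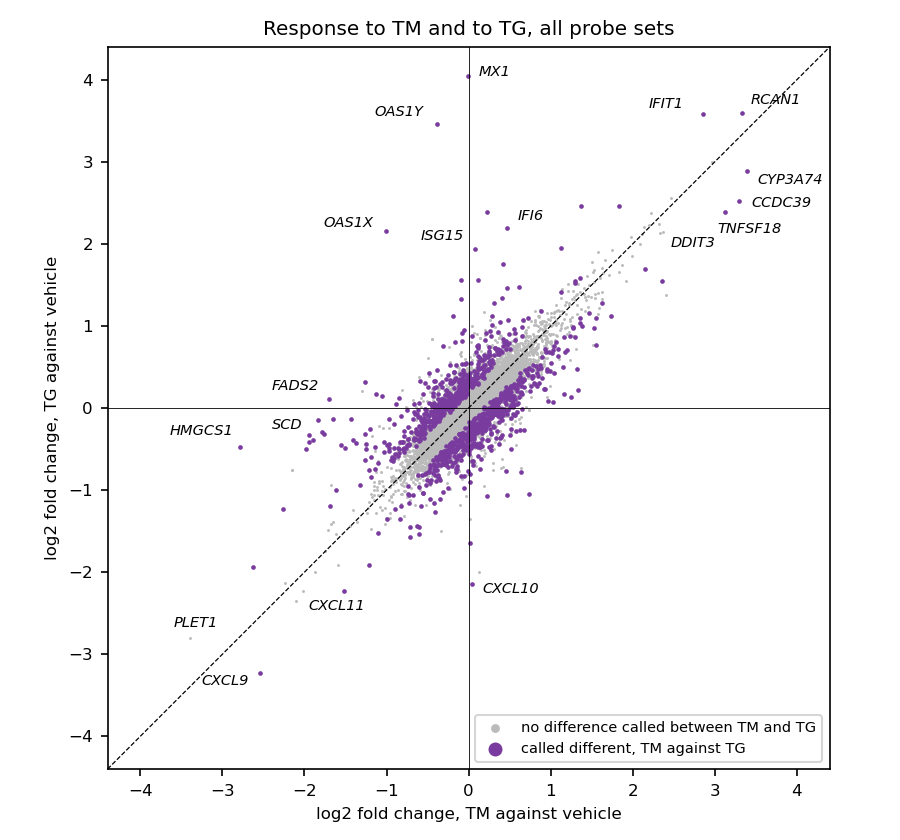
Log2 fold change of all 24333 probe sets with TM (horizontal axis) and with TG (vertical axis), each against vehicle; purple points are the 1058 probe sets called different between TM and TG, and the dashed line marks equal change. Most changed probe sets lie along the line, while MX1 and CXCL10 changed with TG and lie near 0 on the TM axis, and HMGCS1, SCD and FADS2 lie far left of it.

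TM was set against TG directly, to ask where the responses to both stressors differ. Of the fatty acid synthesis genes, 8 of 23 were lower with TM than with TG, and of the cholesterol genes 19 of 24, HMGCS1 by 4.95-fold at 9.30 ± 0.12 (SD, n = 5) against 11.61 ± 0.19 (SD, n = 5). The interferon-induced antiviral genes MX1, OAS1Y, OAS1X and ISG15 were lower with TM than with TG, MX1 by 16.6-fold at 6.16 ± 0.17 (SD, n = 5) against 10.21 ± 0.30 (SD, n = 5). CXCL10 was 4.58-fold higher with TM, at 10.95 ± 0.08 (SD, n = 5) against 8.75 ± 0.27 (SD, n = 5). With TM, 9 of 29 ER-Golgi transport genes were lower, while 5 of 18 PERK-ATF4-CHOP targets and 5 of 20 amino acid genes were higher and ERO1A of the former was lower. In limma, 1058 probe sets passed, 557 higher and 501 lower with TM, and the doses of TM and TG are not matched in any unit.

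The groups were apart for 1533 probe sets, or 6.30% where chance gives 0.794%, and 43 differed by at least 2-fold, 10 higher and 33 lower with TM. In the authors' deposited table, 3456 probe sets had an unadjusted p under 0.05 for this comparison, and 976 after Benjamini-Hochberg adjustment. The count of 1058 moved to 555 when arrays were centred on their medians and to 1819 with a covariate for the width of each array's values. The balance of 557 higher and 501 lower was 699 and 429 without TM array 4, and it turned without TM array 2 (390 and 420) or 3 (393 and 397) or TG array 1 (468 and 558) and with cyclic loess (700 and 719).

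With TM signals near or below the lower quartile of the arrays, so that sizes are uncertain, the genes furthest below TG were MX1 (SE 0.134, adjusted p = 2.13e-10), OAS1Y, 14.3-fold lower (SE 0.209, adjusted p = 2.39e-08), and its neighbour OAS1X, 8.99-fold lower (SE 0.251, adjusted p = 1.35e-06). HMGCS1 came next (SE 0.086, adjusted p = 5.11e-10). The ubiquitin-like modifier gene ISG15 was 3.63-fold lower, FADS2 3.5-fold, the interferon-induced gene IFI6 3.31-fold and ID1, an inhibitor of helix-loop-helix factors, 3.22-fold. Above TG, beside CXCL10 (SE 0.106, adjusted p = 5.08e-09), stood NKG2A, a receptor gene of lymphocytes with close relatives that the deposited table names KLRC1 (adjusted p = 0.00127). It lay at 6.26 ± 0.35 (SD, n = 5) with TM and at 4.6 ± 0.53 (SD, n = 5) with TG, below the lower quartile of the arrays, so the size of this difference is uncertain. Then came the calcium-binding protein gene GCA at 1.29, BIRC3 at 1.12, the procollagen protease gene ADAMTS3 at 1.01, the cell cycle inhibitor gene CDKN2B at 0.99, the activin subunit gene INHBA at 0.95 and the glucose transporter gene SLC2A3 at 0.94. The 5 TM and the 5 TG arrays did not overlap for any of these genes.

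**Figure D3:**
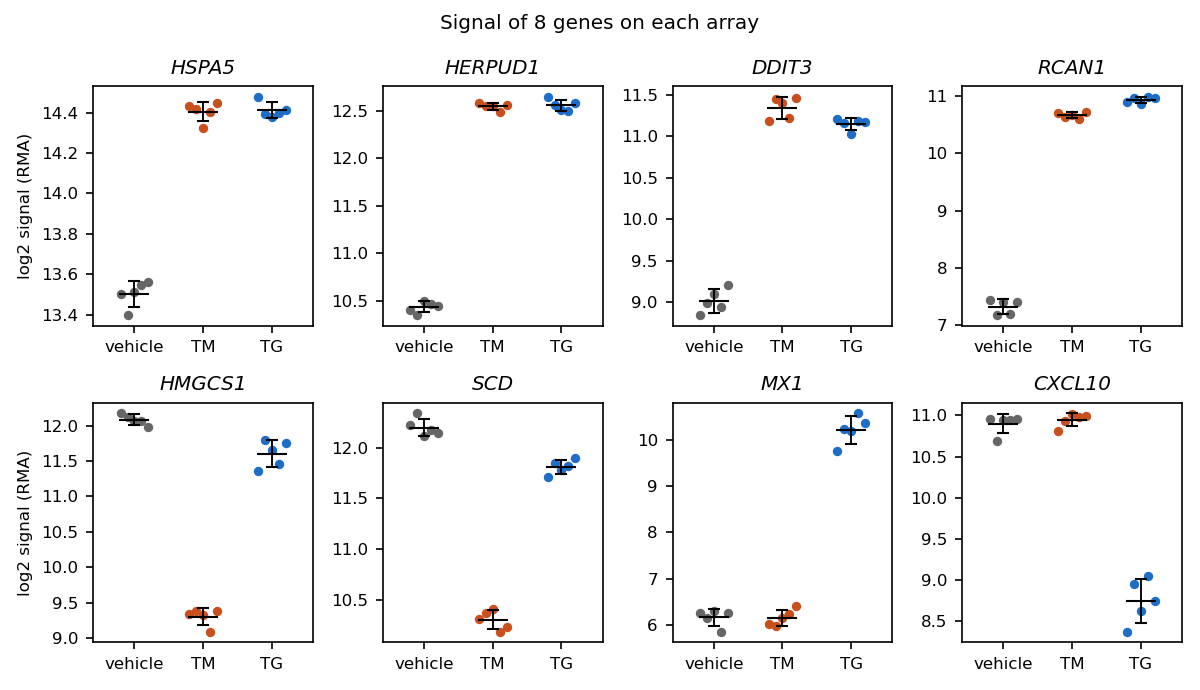
Log2 RMA signal of 8 genes (vertical axes, each with its own range) on each of the 5 arrays per group; dots are arrays, horizontal marks the mean and bars the SD. HSPA5, HERPUD1, DDIT3 and RCAN1 lie higher with both compounds, HMGCS1 and SCD lowest with TM, and MX1 and CXCL10 apart with TG.

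Of 24 cholesterol genes, 19 were lower with TM than with TG and none higher (21 and 0 adjusted over the list alone; median -0.83; camera adjusted p = 6.99e-51, and 0.00155 with an estimated correlation). Beside HMGCS1, INSIG1, which retains the sterol sensor in the ER, was 3.05-fold lower (adjusted p = 1.02e-09). Fatty acid synthesis had 8 of 23 lower and none higher (11 and 1 adjusted over the list alone; adjusted p = 6.69e-08, and 0.00275 with an estimated correlation), with SCD 2.84-fold lower. ER-Golgi transport had 9 of 29 lower and none higher (13 and 0 adjusted over the list alone; adjusted p = 1.9e-08, and 0.0295 with an estimated correlation), with the coat protein genes COPG1 at -0.52 and SEC13 at -0.50. Amino acid genes were higher with TM in 5 of 20 cases and none was lower (10 and 0 adjusted over the list alone; adjusted p = 1.6e-07, and 0.0295 with an estimated correlation), with the transporter genes SLC3A2 at 0.62 and SLC1A5 at 0.49. PERK-ATF4-CHOP targets were higher in 5 of 18 cases and lower for ERO1A, the same adjusted over the list alone (adjusted p = 0.000148, and 0.0295 with an estimated correlation), with the glutathione-degrading enzyme gene CHAC1 at 0.45.

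**Figure D4:**
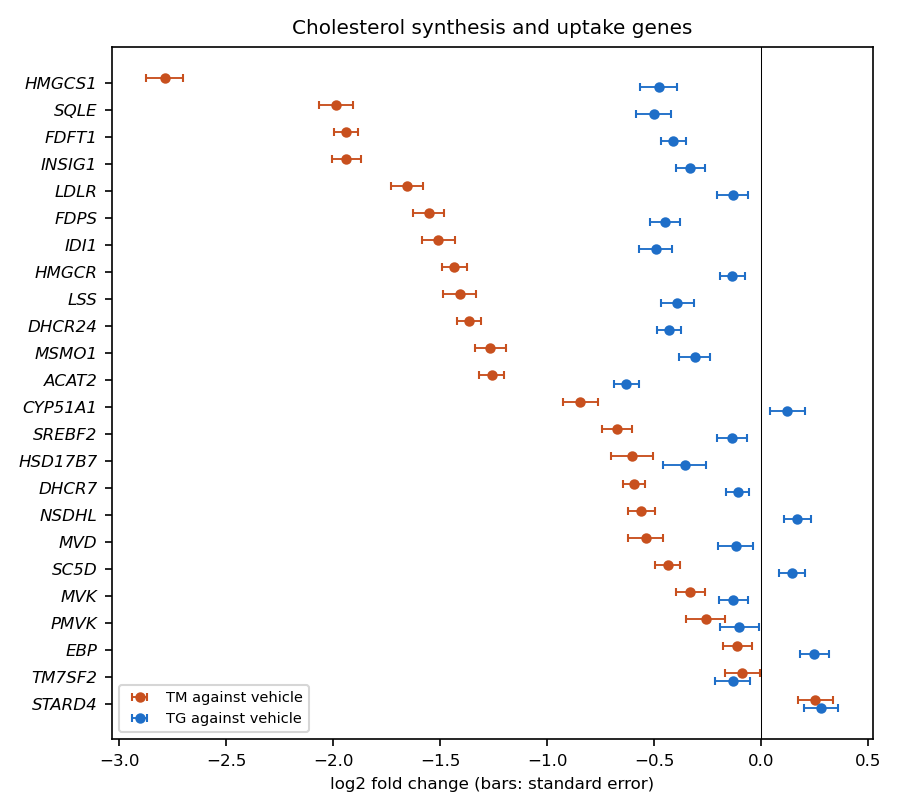
Log2 fold change against vehicle (horizontal axis) of the 24 measured genes of cholesterol synthesis and uptake, with TM in orange and TG in blue and bars for the standard error. With TM the points run from -2.79 for HMGCS1 to 0.25 for STARD4, while with TG they lie between -0.63 for ACAT2 and 0.28 for STARD4.

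The main ER stress genes did not pass between TM and TG: the difference was -0.01 (SE 0.048) for HSPA5, -0.03 (SE 0.043) for HSP90B1, -0.01 (SE 0.049) for HERPUD1, 0.19 (SE 0.077, adjusted p = 0.23) for DDIT3, 0.09 (SE 0.053) for ATF4, 0.04 (SE 0.069) for ATF3, 0.11 (SE 0.100) for FGF21 and 0.03 (SE 0.056) for ATP2A2. XBP1 (adjusted p = 0.999) and ALB (adjusted p = 0.963) did not pass either. ASNS was at 0.17 (adjusted p = 0.0663), and passed in 7 of the alternatives tried, among them without TG array 1 (0.0416). TRIB3 was higher with TM by 0.45 (adjusted p = 0.024), a call that ended without TM array 3 (0.0541) or 5 (0.0721) or TG array 2 (0.067) or 4 (0.0526), or without TM array 4 and TG array 1 together (0.0553). DPAGT1 was higher by 0.26 (adjusted p = 0.0247), a call that ended without TM array 1 (0.0725) or 3 (0.0564) or TG array 2 (0.0694), 3 (0.0594) or 5 (0.0639).

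A further 5 lists passed camera between TM and TG but not with an estimated correlation. ER-associated degradation had 4 of 22 lower and none higher (7 and 0 adjusted over the list alone; adjusted p = 0.263 with an estimated correlation), with EDEM1 at -0.37. The tRNA synthetases had 3 of 18 higher (6 adjusted over the list alone; adjusted p = 0.263 with an estimated correlation). Among these were TARS1 and the tRNA export gene XPOT, which is on that list. Both calls ended with median centring (limma adjusted p = 0.0545 and 0.155), and that of XPOT also with the replicate block (0.104). Acute phase genes had 7 of 28 higher and CCL5 and LIF lower (9 and 2 adjusted over the list alone; adjusted p = 0.0565 with an estimated correlation), with PTGS2 at 0.81 and the chemokine gene CCL5 at -0.99. NRF2 targets had 7 of 22 lower (10 lower and 2 higher adjusted over the list alone; adjusted p = 0.0759 with an estimated correlation), with the sulfiredoxin gene SRXN1 at -0.41. Heat shock genes had 1 higher and 1 lower of 19, HSPA1A and HSPB8 (4 and 1 adjusted over the list alone; camera adjusted p = 0.0487, and adjusted p = 0.455 with an estimated correlation). That call ended without TM array 1 (0.0958), 2 (0.103), 3 (0.0588) or 5 (0.14) or TG array 1 (0.131), 3 (0.0946) or 4 (0.0629), with cyclic loess (0.0632), with the width covariate (0.0528) and without the dimmest probe sets (0.106). Fry did not call the heat shock list either (adjusted p = 0.0935).

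Between TM and TG, fry called 3 lists that camera did not. Calcium handling (fry adjusted p = 0.0149) was lower with TM in it, and gluconeogenesis (0.0132) and fibroblast genes (0.00705) were higher. Together with these, the remaining 15 lists did not pass camera, whose adjusted p follows. Those of the ER were chaperones with 1 higher, DNAJC3 at 0.31, and 2 lower of 27 (2 and 4 adjusted over the list alone; adjusted p = 0.714), N-glycan synthesis with 3 and 3 of 32 (6 and 5 adjusted over the list alone; 0.796) and ALG1 at -0.33, calcium handling with 1 and 3 of 24 (1 and 4 adjusted over the list alone; 0.176) and RCN3 at -0.37, and translocation (0.362) and the sensors (0.182) with none, the same adjusted over the list alone. Of the metabolic lists, fatty acid oxidation had 1 lower, CPT1A (0.911), hepatocyte markers 1 lower, HNF1A (0.949), both the same adjusted over the list alone and both with a positive median beside a negative mean and test, and gluconeogenesis 2 higher, SLC2A2 and GOT1 (3 and 1 adjusted over the list alone; 0.176). Of the growth and death lists, p53 targets had 2 higher, the kinase gene PLK2 at 1.71-fold and the growth arrest gene GADD45A at 1.4-fold, and 2 lower, the same adjusted over the list alone (0.377). Apoptosis regulators had 2 higher and 1 lower (3 and 2 adjusted over the list alone; 0.562), the cell cycle 3 lower, the same adjusted over the list alone (0.176), and autophagy 2 higher, among them ATG3 at 0.35, and WIPI1 lower at -0.30 (3 and 2 adjusted over the list alone; 0.362). Fibroblast genes had 3 higher, among them COL3A1 at 0.41 and TAGLN at 0.33 (3 and 1 adjusted over the list alone; 0.176), cholangiocyte genes none (0.259) and endothelial and macrophage genes 1 lower, LYVE1 (0.495, but 0.0319 without the dimmest probe sets, where the list passed downward), both the same adjusted over the list alone.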

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

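The tests of array width and of the replicate number below were chosen after the values were seen. Within each group of 5 arrays, a named gene, or the median or interquartile range of the arrays, was set aside when the gap between the farthest array and the next one was more than 0.71 of the group's range. Of 375 groups, 369 of them for 123 genes and 6 for the array medians and interquartile ranges, 35 passed that ratio, where about 19 would by chance. All 35 were groups of a gene. TG array 1 and vehicle array 2 each held 8 of them, TM array 4 held 6, and TM array 3 and vehicle array 5 held 3 each. The ratio is the value given with each gene.

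On TG array 1, OAS1Y lay at 8.81 against 9.67 to 9.89 on the other TG arrays (ratio 0.799) and IFI6 at 11.27 against 11.85 to 11.93 (0.883). The same array was lowest for CA3 at 8.32 against 8.77 to 8.86 (0.831), for TKT at 10.08 against 10.26 to 10.31 (0.797) and for CXCL11 at 5.39 against 6.02 to 6.22 (0.759). It was also lowest for SLC2A2 at 6.79 against 7.03 to 7.11 (0.751), for APOA1 at 8.36 against 8.74 to 8.88 (0.740) and for FABP3 at 10.53 against 10.89 to 11.04 (0.712). On TG array 3, DERL3 was highest at 10.52 against 10.27 to 10.30 (0.854) and PCK2 at 11.31 against 11.19 to 11.22 (0.761). On TG array 4, PLET1 was lowest at 8.24 against 8.97 to 9.10 (0.846) and PREB at 10.20 against 10.31 to 10.36 (0.712).

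On TM array 4, COPG1 was lowest at 10.66 against 10.75 to 10.76 (0.863), HMGCS1 at 9.09 against 9.33 to 9.38 (0.824) and HSPH1 at 9.84 against 10.09 to 10.16 (0.785). CCDC39 was lowest there at 8.55 against 8.94 to 9.05 (0.783), CXCL9 at 6.70 against 7.19 to 7.34 (0.770) and KRT6A at 4.46 against 5.05 to 5.26 (0.739). On TM array 3, CCL5 was lowest at 6.72 against 7.22 to 7.39 (0.754), while BMF was highest at 8.48 against 8.27 to 8.32 (0.749) and XBP1 at 12.88 against 12.77 to 12.80 (0.727). On TM array 2, TAGLN was lowest at 12.41 against 12.48 to 12.50 (0.726).

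On vehicle array 2, CXCL10 was lowest at 10.69 against 10.94 to 10.96 (0.924), SEC13 at 11.28 against 11.46 to 11.50 (0.836) and IFI6 at 9.17 against 9.59 to 9.73 (0.741). GCA was lowest there at 8.79 against 8.88 to 8.91 (0.732) and SDF2L1 at 9.46 against 9.66 to 9.73 (0.726). The same array was lowest for KRT19 at 13.17 against 13.36 to 13.43 (0.719), for CRELD2 at 8.83 against 9.17 to 9.29 (0.719) and for PREB at 9.46 against 9.74 to 9.84 (0.718). On vehicle array 5, OAS1X was lowest at 5.67 against 6.24 to 6.35 (0.828) and CA3 at 10.62 against 10.86 to 10.94 (0.759), while COL3A1 was highest at 12.22 against 11.93 to 12.00 (0.750). ALDH1L2 was lowest on vehicle array 1 at 9.28 against 9.43 to 9.48 (0.760), and CCDC39 on vehicle array 4 at 5.20 against 5.66 to 5.82 (0.752).

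Arrays of one group deviated along one shared axis, which held 26.6% of the variance within groups. Over the 15 arrays, the score on this axis followed the interquartile range of each array's values, both centred by group, with a Pearson r of 0.965 and a Spearman rho of 0.957 (permutation p = 1e-05 for both, the smallest that the permutations can give), and r was 0.933 without the 2 arrays farthest from the median. Probe sets of the brighter part of the arrays loaded upward in 71.1% of cases and those of the dimmer part in 29.5%, so a candidate explanation is a stretch or squeeze of the scale on single arrays. The axis and the interquartile range were computed from the same values, so their correlation is not an independent test of it. A day or batch marked by the replicate number was tested as well and stays open: the numbers held 55.2% of the variance of the score (permutation p = 0.145). No biological explanation was tested.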

How the results depend on the processing

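The covariate for the width of each array's values and the fit without TM array 4 and TG array 1 were chosen after seeing the data. With a 2-fold minimum added, 234 probe sets passed for TM, 227 for TG, 43 for TM against TG and 139 in the same direction for both, since fewer can meet a stricter rule. The count for TM against TG moved to 555 with median centring and to 1819 with the width covariate, and the cause was not tested. The overlap moved to 2333 with the vehicle arrays divided, where fewer arrays stood in each comparison. With an estimated correlation, the number of lists moved to 9 for TM and to 5 for TM against TG. The lists that dropped out had estimated correlations from 0.048 to 0.204, above the preset 0.01, and camera allows a list more variance the higher this correlation. How much of the move this accounts for was not tested.

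The other counts stayed within 1.5 times the reported ones, from 3881 (median centring) to 6180 (width covariate) for TM, from 4017 to 6257 for TG under the same settings, from 743 (the 10 arrays of both groups alone) to 1475 (trended and robust variances) for TM against TG, and from 2759 to 4538 for the overlap. With single arrays left out, the counts ran from 4479 to 4883 for TM, 4523 to 4970 for TG, 774 to 1128 for TM against TG and 3250 to 3600 for the overlap, and the lists from 18 to 20, 13 to 14 and 9 to 10. The median change of all probe sets stayed between -0.027 and 0.003 under each scaling. In the settings run for them, no named gene or list turned its direction where it passed with or without the change of setting. Some that passed in neither did turn, among them ALB, and the lists of hepatocyte markers and fatty acid oxidation for TM against TG. The balance of higher and lower calls did turn, in 7 of 23 alternatives for TM, 6 of 23 for TG, 5 of 23 for TM against TG and 8 of 26 for the overlap. With cyclic loess it was 2817 higher and 2557 lower for TM, 2771 and 2616 for TG, and 700 and 719 for TM against TG.

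In the sample titles each replicate number holds 1 array of each group in running order, and what the number marks is not given. The replicate numbers were not read as pairs: 7 of 15 same-numbered pairs of arrays correlated above 0.1 once their group means were removed (from -0.111 to 0.304), and only 1 array correlated best with its own number in both other groups. With the number as a block, the counts were 5066 for TM, 5125 for TG, 955 for TM against TG and 3661 for the overlap, and the list calls were the same. As a random block (consensus correlation 0.0924) they were 5366, 5424 and 1268.

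Single genes were not run with the random block, the 10 arrays of each pair of groups, 1 probe set per gene or the 2-fold minimum. Genes that changed less than 2-fold, HSPA5 among them for TM, would not meet that minimum. In the other alternatives, all 68 genes named for TM kept their side of the threshold where they were measured. For TG, 72 of 73 did, FGF21 being the exception. For TM against TG, 46 of 59 did. The 13 others were TRIB3, ASNS, DPAGT1, FKBP14, NPLOC4, TARS1, XPOT, ALG6, RCAN1, ME1, CASP6, MCM3 and CDC25A, and 10 of them lost the call with median centring, 3 with the replicate block and 6 without TM array 4 and TG array 1. Leaving out single arrays ended the call in 50 of 590 cases and added 1.

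Signal limits what can be said of dim and bright probe sets. The lower quartile of the arrays lay between 6 and 6.21. In at least 1 group, ALB, CCDC39, TNFSF18, CXCL11, KRT6A, OAS1X, OAS1Y, NKG2A, MX1 and SERPINI1 had a mean below 6.21, and the deposited data give no background level, so the size of their changes is uncertain. HSPA5 and HSP90B1 lay at 14.41 and 14.16 with TM, near the highest value of 14.98, which leaves little room for a larger rise to show.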

Other observations

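The interferon gene list, the gene ontology terms and the tests of single arrays, paralogs, ER stress strength and rescaling below were chosen after the values were seen. The test by brightness and the splits of the arrays were fixed before them. A list of antiviral genes that cells switch on in response to interferon was drawn up once MX1, OAS1Y and other leading genes of it had been seen, and it contains them, so no test of the whole list is given. Of 29 measured members, 21 rose and only HERC6 fell with TG (median 0.65), while 4 rose and 3 fell with TM. RIGI, a sensor of viral RNA, rose by 1.76 with TG, the transcription factor gene IRF9 by 1.56, IFI27 by 1.56, the ISG15 protease gene USP18 by 1.33 and the antiviral gene RSAD2 by 0.81. Their TG arrays all lay above the vehicle arrays. Against this rise, the chemokine genes CXCL9, CXCL10 and CXCL11, which interferon also induces but which are not on the list, fell with TG.

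Of 1130 gene ontology terms with 10 to 300 measured genes, 21 moved up and 35 down with TM, 20 up and 34 down with TG, and 8 up and 12 down between TM and TG, while 0, 0 and 2 passed with an estimated correlation. RNA splicing genes fell in 61 of 112 cases and rose in 4 with TM (adjusted p = 1.77e-10, and adjusted p = 0.761 with an estimated correlation), and fell in 64 and rose in 4 with TG (adjusted p = 1.66e-11, and 0.724 with an estimated correlation), among them the splicing factor genes SRSF7 and SNRPD1. GPI anchor biosynthetic process genes, which build the lipid anchor of surface proteins, rose in 13 of 19 cases with TM (adjusted p = 0.371 with an estimated correlation) and 9 with TG (0.616 with an estimated correlation), PIGA and PIGV among them. Proteasome assembly genes fell in 9 of 10 cases with TM (adjusted p = 0.371 with an estimated correlation) and 5 with TG (0.656 with an estimated correlation), among them PSMG1 and PSMG2. Of 13 sphingolipid biosynthetic process genes, the ceramide synthase genes CERS2, CERS5 and CERS6 and the phosphatase gene PLPP1 were higher with TM than with TG and none was lower (median 0.13; adjusted p = 3.51e-06, and 0.0409 with an estimated correlation).

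Of the listed antiviral genes, 20 of 29 were lower with TM than with TG and none was higher, while CXCL9 and CXCL10, which are not on the list, were higher with TM (by 0.68 on the log2 scale and by 4.58-fold). The median difference over all 29 was -0.509, and with each array left out in turn it stayed between -0.554 and -0.499, which argues against a single array. Probes shared between paralogs were tested on the 6 members without a relative on the list, leading genes aside, and not marked for cross-hybridization. Of these, 4 were called lower with TM with the groups apart: USP18 (-1.42), RSAD2 (-0.89), EIF2AK2 (-0.61) and CMPK2 (-0.365). XAF1 and EPSTI1 were not called (limma adjusted p = 0.0556 and 0.146). This argues against shared probes for those 4 genes. For the 22 with a relative, shared probes stay open and the gene that gave the signal is less certain. Stronger ER stress with TG stays open: the 185 genes of the 8 ER lists had a median difference of -0.027 (quartiles -0.138 and 0.076), with ER-Golgi transport lower with TM (median -0.172, adjusted p = 0.0295 with an estimated correlation) and PERK-ATF4-CHOP targets higher (0.131, adjusted p = 0.0295). Another effect of TG may also underlie the difference and was not tested.

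The lower cholesterol genes with TM than with TG had a median difference of -0.833 over 24 genes. It was -0.842 with cyclic loess, -0.825 with median centring and -0.838 with the width covariate, so further rescaling of the arrays did not remove it. These settings were applied to the deposited RMA values. They cannot test the authors' normalization itself, which stays open. With single arrays left out it stayed between -0.865 and -0.794. A shift that depends on brightness is argued against by 0 of 10000 random lists matched for brightness with a median as low, the lowest being -0.14. A response of this pathway to TM that TG gives to a lesser degree may remain, as a hypothesis found and tested on the same data.

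The arrays were also split in other ways. For TM against vehicle, 1 of the 100 splits, the real one, reached 4979 probe sets, and the highest other gave 1. For TG, 1 of the 100 splits reached 5063 and the highest other gave 1. For TM against TG, 1 of the 100 splits reached 1058 and the highest other gave 519. For the overlap, 1 of the 100 splits reached 3633 and the highest other gave 0. The smallest share that 100 splits can give is 1 of 100. For TM, TG and TM against TG, the real split alone reached the count, which argues against chance among these arrays. Whether the arrays were separate cultures is not given. The splits for the overlap mixed the arrays of all groups, which removes both treatment effects. Hardly any probe set could then be called in both comparisons, so these splits cannot show whether TM and TG share genes by chance.

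The number of lists called by camera with a preset correlation was less secure. For TM, 3 of the 100 splits, the real one among them, reached 18 lists, and the highest other also gave 18. This is under the limit of 5 in 100 fixed beforehand, but the other splits called a median of 7 lists. Chance is therefore not excluded for each of the 18. Splits with a camera p as small numbered 21 of 100 for the cell cycle, 12 for p53 targets, 11 for heat shock genes and 6 for the sensors. For ER chaperones and cholesterol genes it was the real split alone. For TG, 10 of the 100 splits reached 13 lists, the highest other giving 14, and for TM against TG 5 of the 100 splits reached 10, the highest other giving 12, so chance cannot be excluded for these counts. With an estimated correlation, the real split alone reached 9, 9 and 5 lists, and the highest other gave 0, 0 and 1.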
